A study of Oncorhynchus mykiss with 23 samples.

How the data were processed

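Liver RNA of 23 rainbow trout was hybridised to 1-colour Agilent expression arrays, 1 array per fish. Per the labels, RNA was extracted with TRIzol and labelled with the dye Cy3. The fish were grouped by the labelled diets of their parents into NN (6 arrays), HN (5 arrays), NH (6 arrays) and HH (6 arrays), where the first letter is the mother's diet, the second letter the father's, N the control diet and H the diet high in carbohydrate and low in protein. The labels give the sex of each fish (18 females and 5 males) but not its tank or family. The design text speaks of 6 livers per condition, 5 HN arrays were analysed here, and the number of tanks it gives (9) does not match 3 tanks for each of the 4 conditions. P-values measure the spread between these fish. With 3 tanks for each condition, some fish of each group must have shared a tank, so the fish are not fully independent replicates. Which fish shared a tank, and whether any shared parents, was not known.

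Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09, and each deposited file holds 62976 features. The processed signal used here is a spot intensity on a linear scale, background-subtracted and detrended within the array by Feature Extraction per the file headers, with no step between arrays. Mean, median and local background intensity per the file headers are raw pixel brightness. The authors' deposited value table is on a log2 scale: set against the scanner values, each column equalled log2 of the median spot signal minus 1 constant per array, within a range of about 1e-05. What that constant is, and which filter left 53321 features (52892 probes), stays unknown. No direction is involved, as each column belongs to 1 array. The column medians of that table lay between -0.58 and -0.35. The submitters' processing notes name limma without a version. Any other step of the authors is not given in the sources used here.

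The 61657 non-control features gave 61175 probes. The processed signals were taken as log2 minus the log2 of each array's own 75th percentile over non-control features, the 117 feature values with an outlier flag were left out, and spots of 1 probe were averaged. No spot was saturated (0 features). A probe was tested when it was well above background on at least 4 arrays of at least 1 group, which left 44627 probes and set aside 16548. The precision of each value is limited by the number of arrays. Values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per group over all 23 arrays, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probes within a comparison, with 0.05 as the threshold. The comparisons were HN, NH and HH against NN, HH against NH, HH against HN, the interaction (HH minus HN minus NH plus NN), and male against female with group and sex in the model. The labels name limma but no model, so this model was chosen here. Where every array of a group was not well above background, a fold is given as "at least N-fold", the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of a probe well above background.

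Names are those of the array design in the files. Of the probes on the array, 46255 carry only the number of a transcript model, and 0 of these numbers were found in the reference table of locus tags, accessions and symbols. A further 5649 carry a LOC number of another species, 2635 a contig number, 1509 a name that more than 40 contigs share, 676 a locus name and 170 a transposon or ribosomal RNA. The remaining 4281 carry a gene name. Of the 2864 names, 897 equal a symbol of the reference table, and the other names are kept as the files give them. Names were given by rule: among passing probes with a gene name, 1 probe per gene (the 1 with the highest mean), the 10 with the largest rise and the 10 with the largest fall, plus up to 4 passing members of each gene list. Where fewer than 5 named genes passed, the 5 highest and 5 lowest moderated statistics were added as values that did not pass. Members of a fixed set of metabolic genes were also given where they were measured, except 1 that is not reported here. At most 2 unnamed probes are given each way.

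Gene lists were fixed for 33 pathways, complexes and marker sets. Of these, 29 had a measured member, 20 had at least 3 and were tested, and 9 had 1 or 2 members. The 4 without a measured member were mitochondrial fatty acid oxidation, estrogen-responsive egg protein, exocrine pancreas marker and adipose marker. File names that follow protein names were paired with list symbols by hand for 55 names, after the files were seen but without use of any value. Each list was tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. The Pearson and Spearman correlations of the HN against NN with the HH against NH changes, and of the NH against NN with the HH against HN changes, were set against 100 random regroupings of the fish, since neither pair shares a fish. The groups, tests, gene lists, naming rule and the alternatives below were all fixed before the data were examined. The comparisons of all fish by the father's and by the mother's diet, the fit of the 10 arrays on shared slides without the slide term, the list tests with sex and an estimated correlation together, and a filter on dim probes blind to the groups (well above background on at least 4 arrays of all), were added later.

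The arrays lay on 17 slides, 6 with 2 arrays and 11 with 1, and were scanned on 3 days (7, 8 and 8 arrays), each of which held all 4 groups. HH and NN shared 5 slides. The slide row of the array went with the mother's diet: row 1 held 5 of 5 HN, 5 of 6 HH, 1 of 6 NN and 1 of 6 NH arrays. The column went in part with the group as well: HH 1, HH 2, HH 3, HH 5 and HH 6 lay in column 4 and HH 4 in column 3. HN 1, HN 2 and HN 4 lay in column 3, HN 3 in column 2 and HN 5 in column 4. NN 2, NN 3, NN 6 and NH 4 also lay in column 4. Column was in no model. Alternatives were quantile and cyclic loess normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, probes above background on all arrays, a minimum change of 1.5-fold, only the arrays of the groups compared, sex as a covariate, females only, slide as a random or fixed block, array row, scan day, array weights, the mean of all probes of a gene for lists, and leaving out each array in turn. Tables were handled with jsonlite 2.0.0 and the R package data.table in version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

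The fits were tested on simulated data in which 200 of 44627 probes were changed, 50 at each of 4 sizes. For HH against NN, 10%, 52%, 86% and 98% of the probes changed by 0.5, 1, 2 and 4 on the log2 scale were recovered, with 10 false calls. For male against female the shares were 0%, 16%, 74% and 98%, and HH against NN with sex as a covariate gave 9 false calls. With slide as a fixed block the HH against NN shares were 0%, 0%, 52% and 94%. NH against NN, simulated without change, gave 0 false calls, and for the lists 1 was called where 1 had been shifted. The simulated probes were drawn independently of each other, each with the same spread in all groups. The simulation thus does not show how correlated genes, unequal spread or shared tanks and slides affect the calls in the real data.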

Results

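Expression in the liver of 23 rainbow trout was measured on 1-colour arrays that held 61175 probes besides controls. The series asks how the diet of the parents before spawning affected the liver of offspring fed a plant-based diet. The parents had been fed a control diet (63.89% protein and 0% carbohydrate) or a diet high in carbohydrate and low in protein, called HC/LP (35.30% carbohydrate and 42.96% protein), the females through a whole reproductive cycle and the males for 5 months. The offspring were kept at 17 °C and, per the design text, had 6 months of commercial diet and then 3 months of the plant-based diet, while the treatment protocol mentions only the 6 months. Groups are named by the mother's diet and then the father's, with N for control and H for HC/LP. NN held 5 females and 1 male, HN 1 female and 4 males, and NH and HH 6 females each, so the sex of the fish went with the HN group.

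The 75th percentile of the processed signal lay between 60.6 and 249.9 over the arrays. The share of features well above background was 70.5% ± 9.92 (SD, n = 6) in NN, 70.2% ± 13.1 (n = 5) in HN, 67.9% ± 7.57 (n = 6) in NH and 72.5% ± 7.47 (n = 6) in HH, with single arrays from 50.9% to 84%. Across the 28294 probes well above background on all arrays, the first principal component held 14.7% of the variance. The correlation between arrays, taken across probes, which are not independent replicates, had a median of 0.968 over the 55 pairs of the same group and 0.965 over the 198 other pairs. Of the 44627 probes tested, 34093 carried only a transcript model number and 3011 a gene name, for 2154 named genes.

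The first question was how offspring of 2 HC/LP parents differed from those of 2 control parents. In HH livers the desaturase gene FADSD5, named for the Δ5 step in the making of long-chain polyunsaturated fatty acids, rose by 4.13 ± 0.84 (log2, SE, n = 6 against 6, adjusted p = 0.026). ECM1, which encodes a secreted matrix protein, fell by 3.27 ± 0.50 (adjusted p = 0.0051). Its mean went from a log2 level of 8.45 ± 0.76 (SD) in NN to 5.18 ± 0.40 in HH. The major histocompatibility class I gene ONCMYK-UBA fell by 1.23 ± 0.21 (adjusted p = 0.012), and C5AR, named for the receptor of complement C5a, fell by 2.38 ± 0.48 (adjusted p = 0.024), with 1 of 6 HH fish well above background. CIO1B rose by 2.42 ± 0.38 (adjusted p = 0.0065) and PTA1 by 5.11 ± 1.15 (adjusted p = 0.047), the latter from -4.74 ± 1.73 to 0.37 ± 1.48. PTA1 was well above background in only 1 of 6 NN fish, and CIO1B in 3 of 6. In each of these genes, all 6 HH fish lay on the side of the change from the NN mean. FADSD5 was well above background in only 3 of 6 NN fish, and HH 1 (-3.71) and HH 2 (-4.04) lay at or near the NN values while HH 3 to HH 6 lay from 1.37 to 2.53. The SE pools the spread of all groups, while the SD of FADSD5 was 0.38 in NN and 2.94 in HH.

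Of the 44627 probes, 200 passed in HH against NN, 71 higher and 129 lower, with a median absolute log2 change of 1.54 and changes from -3.44 to 6.72. Of these 200 probes, 139 were transcript models without a name and 18 were named genes. Among the named genes, RTCB (1.81), VPS41 (1.75), IRK11 (1.46), the kinase gene LRRK2 (1.29), DAB2IPA (1.07), HKR1 (0.95) and NBP1A (0.95) also rose, with SE from 0.21 to 0.40 and adjusted p from 0.021 to 0.046. CR19B (-2.30), the kinesin motor gene KIF3A (-1.65), NMNA1 (-1.05), the tropomyosin gene TPM4 (-0.87) and S25BP (-0.66) also fell, with SE from 0.13 to 0.46 and adjusted p from 0.0096 to 0.040, and in each of these genes 6 of 6 HH fish lay on the side of the change. Transcript models without a name included GSONMT00054907001 (5.79 ± 0.94, adjusted p = 0.0093) and GSONMT00068403001 (4.62 ± 0.85, adjusted p = 0.018), which rose, and GSONMT00025339001 (-3.44 ± 0.50, adjusted p = 0.0041) and GSONMT00021743001 (-3.40 ± 0.65, adjusted p = 0.02), which fell. Other probes of the same gene went a different way or less far for VPS41 (-0.02), NBP1A (-0.06), HKR1 (0.25), C5AR (-0.31), RTCB (0.81), S25BP (0.35 and 0.67), IRK11 (-0.03 to 0.25 over 4 probes) and KIF3A (-0.84 to 0.06 over 5 probes).

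**Figure D1:**
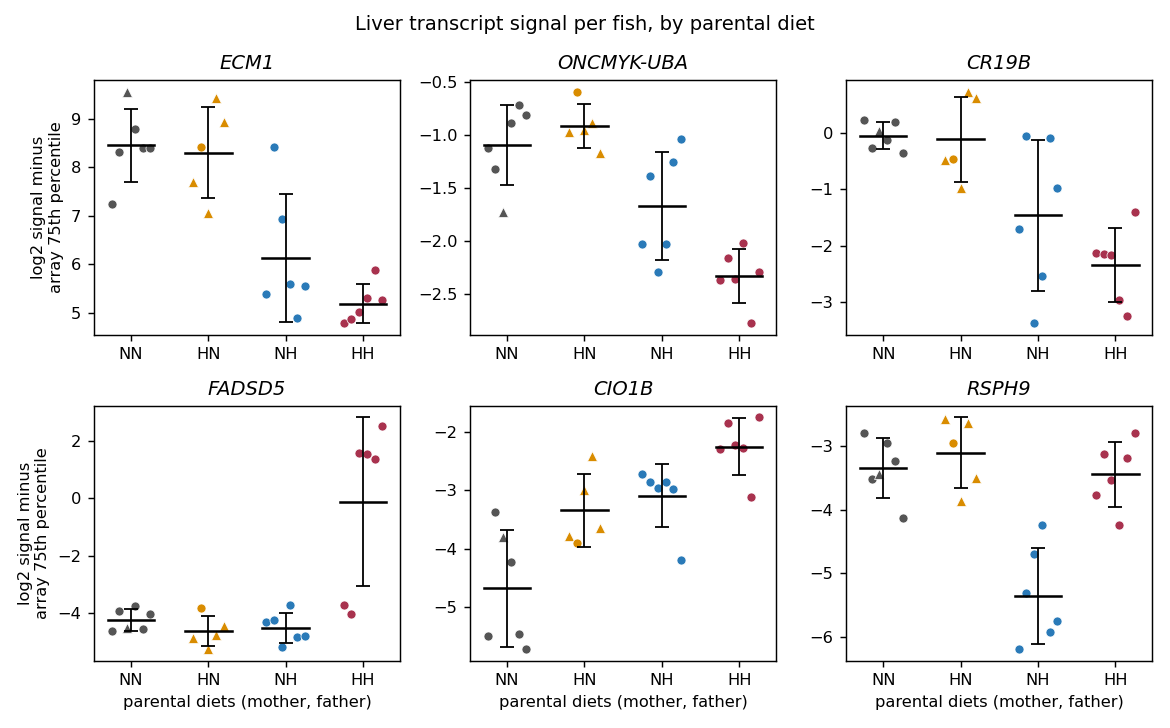
Log2 levels relative to the 75th percentile of each array are plotted for named genes in the 23 fish, by group, with circles for females, triangles for males and bars for the mean ± SD. ECM1 lay at a mean of 8.45 in NN and 5.18 in HH, and FADSD5 lay at -4.25 ± 0.38 in NN and -0.12 ± 2.94 in HH.

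The HH against NN changes had the same direction on each of the 3 scan days for the 18 named genes. Within the 5 slides shared by HH and NN, PTA1 (lowest -0.16), FADSD5 (-0.11) and LRRK2 (-0.33) kept direction on 4, and the other named genes on all 5. These genes were chosen over all of these fish, which pushes such agreement up. In a check that was not planned, 200 probes were chosen on the other days. Of these, 175, 189 and 171 had the same direction on days 1, 2 and 3 (87.5%, 94.5% and 85.5%, against 56.6%, 57.5% and 57.8% of all probes). On days 1, 2 and 3, the values were -3.00, -2.80 and -4.01 for ECM1, 5.62, 3.75 and 3.00 for FADSD5, 2.14, 3.58 and 1.55 for CIO1B, and -1.60, -1.37 and -0.74 for ONCMYK-UBA. With scan day in the model 200 probes passed, 176 of them among the first 200. The named genes HKR1 (adjusted p = 0.052) and NMNA1 (adjusted p = 0.054) missed the threshold. With the row of the array on the slide in the model, 12 probes passed and none of the 18 named genes did (ECM1 -2.77 ± 0.60, adjusted p = 0.11; CIO1B 2.57, adjusted p = 0.06). Over the 200 probes the median absolute change went from 1.54 to 1.48 and the median SE from 0.30 to 0.38. The 5 slides that held 1 HH and 1 NN array gave 10 probes with slide as a fixed block, against 165 for the same 10 arrays without it. ECM1 still passed (-3.43 ± 0.28, adjusted p = 0.038), and the other 17 named genes did not (FADSD5 4.77, adjusted p = 0.14; CIO1B 2.27, adjusted p = 0.096; ONCMYK-UBA -1.23, adjusted p = 0.13). For the same 10 arrays without the slide term, 2 of the 18 named genes passed and 16 did not. For the named genes most losses thus came with the smaller set of arrays, while over all probes the count fell from 165 to 10 with the slide term. Sex in the model left 166 probes, 146 of them among the first 200, and the median absolute change of the 200 was 1.55 after 1.54, with a median SE of 0.32 after 0.30. PTA1 (4.47), VPS41 (1.79), IRK11 (1.42), LRRK2 (1.22), HKR1 (0.95) and NMNA1 (-1.0) then missed the threshold, with adjusted p from 0.052 to 0.069.

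Leaving out 1 array moved the HH against NN count most without NN 4 (68), HH 5 (83), NN 5 (105), NN 1 (120), NN 3 (122), HH 4 (122) and HH 2 (123). ECM1, CIO1B, KIF3A and ONCMYK-UBA passed in all 23 of these fits. FADSD5 did not pass without NN 1, NN 3, NN 4, NN 5, HH 3, HH 4, HH 5 or HH 6 (adjusted p up to 0.071), C5AR without NN 1, HH 2 or HH 5 (up to 0.058; it was too dim to be tested in the 4 fits without NN 2, NN 3, NN 4 or NN 5), and DAB2IPA without NN 4 (0.058) or HH 5 (0.053). The other named genes lost the call in 6 fits (CR19B and TPM4), 7 (S25BP), 8 (NBP1A), 9 (VPS41, IRK11 and NMNA1), 10 (LRRK2), 12 (RTCB), 15 (PTA1) and 18 (HKR1), with adjusted p up to 0.12.

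None of the 20 gene lists tested moved together in HH against NN (camera, 0 lists, smallest adjusted p = 0.72, and 0 lists by fry). In long-chain polyunsaturated fatty acid synthesis, FADSD5 was the 1 of 5 members that passed, and FADSD6 (-0.04), D6FADC (-0.04), ELOV1 (-0.11) and HACD1 (-0.32) did not, so that the list's median was -0.04 while its mean was 0.72 and its test pointed up. Adjusted over the list alone, 5 members passed, against 1 over all probes: FADSD5, the lipid droplet gene MGLL (1.51 ± 0.51), the clock gene PER2 (0.67 ± 0.20), the ATP synthase gene ATP5A1 (-0.70 ± 0.21) and the insulin receptor gene INSRA (-0.58 ± 0.19). MGLL was the only measured member of its list, so that its p (0.0068) had no adjustment there. Cholesterol synthesis and uptake had 1 of 5 members higher (median -0.04), lipoprotein and lipid transport 1 of 3 (-0.34), glycolysis 4 of 7 (0.03), amino acid catabolism 2 of 4 (0.02), oxidative phosphorylation 3 of 10 (-0.11), cytosolic ribosome 25 of 49 (0.01), proteasome 0 of 4 (-0.15), and endoplasmic reticulum stress 3 of 6 (0.03). The medians were 0.03 for heat and oxidative stress, 0.21 for the interferon and antiviral response, 0.02 for acute phase and complement, 0.12 for the circadian clock, -0.26 for growth hormone, IGF and insulin signalling, 0.10 for xenobiotic metabolism, -0.10 for DNA methylation and chromatin, and -0.14 for autophagy. Markers of other cell types had medians of -0.28 (erythrocyte), -0.12 (leukocyte), -0.02 (stromal and endothelial), 0.00 (intestine) and 0.01 (skeletal muscle), and hepatocyte markers 0.02. Of the metabolic genes always given, the glucose-6-phosphatase gene G6PCA.2 (-0.05), SCD5 (-0.44) and DNM3A (-0.10) did not pass.

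The second question was how the HC/LP diet of the father mattered where the mother was fed HC/LP as well. In HH against HN, FADSD5 rose by 4.52 ± 0.88 (n = 6 against 5, adjusted p = 0.040), at least 14.5-fold, since it was not well above background in any HN fish. That change of the mean came from HH 3 to HH 6, as HH 1 (-3.71) and HH 2 (-4.04) lay near HN 2 (-3.84). The SD was 2.94 in HH and 0.53 in HN, which the pooled SE does not show. NPTN, which encodes the adhesion protein neuroplastin, rose by 2.16 ± 0.44 (adjusted p = 0.049), with 0.43 in another probe of the gene. ECM1 fell by 3.13 ± 0.52 (adjusted p = 0.028) and ONCMYK-UBA by 1.42 ± 0.22 (adjusted p = 0.016), each of the 4 genes in the stated direction in 6 of 6 HH fish. In all, 62 probes passed, 19 higher and 43 lower, of which 42 were transcript models without a name. GSONMT00054907001 (5.62 ± 0.99, adjusted p = 0.032) and GSONMT00039314001 (5.45 ± 0.77, adjusted p = 0.0087) rose, and GSONMT00025339001 (-2.97, adjusted p = 0.032) fell. The 5 lowest moderated statistics of named genes that did not pass were those of RTDR1 (-0.97, adjusted p = 0.063), CR19B (-2.24, 0.072), TPM4 (-0.76, 0.11), SLITRK4 (-0.77, 0.12) and PLM (-0.73, 0.13). The 5 highest were those of TSPAN7B (1.16, 0.15), BMPR2B (0.78, 0.15), RASSF1 (0.84, 0.19), AMPH (1.17, 0.22) and HSBP1 (0.83, 0.28).

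HN held 4 males and HH none, and with sex in the model 5 probes passed, 2 of them among the 62. The median absolute change of the 62 probes stayed at 1.65 after 1.67 while the median SE went from 0.32 to 0.46. ONCMYK-UBA still passed (-1.89 ± 0.29, adjusted p = 0.034), and ECM1 (-2.64 ± 0.75, adjusted p = 0.29), FADSD5 (3.99 ± 1.29, adjusted p = 0.36) and NPTN (2.57 ± 0.63, adjusted p = 0.21) did not. By scan day the values were 6.72, 4.02 and 3.12 for FADSD5, -1.46, -4.16 and -3.13 for ECM1, -1.45, -1.30 and -1.48 for ONCMYK-UBA, and 2.57, 2.43 and 1.64 for NPTN. With scan day in the model 38 probes passed, and with array row 29. ECM1 and ONCMYK-UBA passed under both, while the adjusted p was 0.063 and 0.064 for FADSD5 and 0.078 and 0.079 for NPTN. Leaving out 1 array gave 3 probes without HN 4, 6 without HN 2, 8 without HH 3, 10 without HH 2 or HH 5, 12 without HH 4 or HN 5, 19 without HN 1, 25 without NN 4 or NN 6, 28 without HN 3 and 38 without NN 1. ONCMYK-UBA lost the call in 2 of these fits (HN 2 and HN 4), ECM1 in 5 (HN 2, HN 4, HN 5, HH 2 and HH 3), FADSD5 in 13 and NPTN in 17.

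Genes of oxidative phosphorylation were lower in HH than in HN, 8 of 10 members (median -0.23, camera adjusted p = 0.013), and the adjusted p was 0.57 with an estimated correlation and 0.4 by fry. Adjusted over the list alone, 3 of these members passed, ATP5A1 (-0.67 ± 0.22), NDUB7 (-0.43 ± 0.13) and NDUS7 (-0.51 ± 0.18), and 0 did over all probes. The median of the list was -0.01, -0.30 and -0.31 on scan days 1, 2 and 3, -0.22 with scan day in the model (adjusted p = 0.04), -0.23 with array row (adjusted p = 0.016), and 0.09 with sex in the model (adjusted p = 0.46), where its mean was -0.11 and its test still pointed down. Leukocyte markers had a median of -0.22 in the same comparison (4 of 4 lower, adjusted p = 0.28). Without HH 1, HN 2, HH 5 or HN 4 the adjusted p of oxidative phosphorylation was 0.07, 0.18, 0.058 and 0.056. Over all lists, 6 members passed adjusted over the list alone, which included MGLL (1.39 ± 0.53, alone in its list with an unadjusted p = 0.015) and PER2 (0.64 ± 0.21), and 1, FADSD5, passed over all probes.

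The father's HC/LP diet alone was addressed by NH against NN. RSPH9, which encodes a radial spoke protein of cilia, fell by 2.0 ± 0.32 (n = 6 against 6, adjusted p = 0.034), lower in 6 of 6 fish. It was not well above background in any NH fish, so the fall was at least 1.48-fold, and another probe of the gene had -0.43. GSONMT00030247001 rose by 1.43 ± 0.21 (adjusted p = 0.021) and GSONMT00029152001 fell by 1.34 ± 0.21 (adjusted p = 0.034). Of the genes that changed in HH, ECM1 had -2.32 ± 0.50 (adjusted p = 0.12), CIO1B 1.59 (0.19) and PTA1 4.02 (0.30) in NH, none of which passed. These 3 were among the 5 highest and 5 lowest moderated statistics of named genes that did not pass, as were RTDR1 (-1.0 ± 0.20, adjusted p = 0.091), MSI2H (-0.98, 0.12), CBL (-0.68, 0.19), CRLF3 (-0.73, 0.20), TTC13 (1.0 ± 0.21, 0.12), TR1L1 (1.18, 0.29) and PTPR2 (0.62, 0.30). In all, 4 probes passed, 1 higher and 3 lower, and 4283 had an unadjusted p under 0.05, where chance gives 2231. The RSPH9 change was -1.97, -2.49 and -1.52 on the 3 scan days, and its adjusted p was 0.053 with scan day and 0.0051 with array row in the model. With sex it was 0.043, and 7 probes passed. The count was 36 without NH 6, 8 without NN 2, 7 without NH 4 or HH 4, 2 without NN 4 or HH 3, and 1 without NN 1. RSPH9 lost the call without NN 1, NN 3, NN 4, NN 5, NH 1, NH 2, NH 5, HN 2 or HH 3 (adjusted p up to 0.14). Camera called 0 lists (smallest adjusted p = 0.6), and fry called 0 as well. Adjusted over the list alone, MGLL (1.39 ± 0.51) and the DNA topoisomerase gene TOP2A (-2.22 ± 0.58) passed, against 0 members over all probes. Each was the only measured member of its list, so these are unadjusted p-values (0.012 and 0.00088).

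The mother's HC/LP diet was addressed by HH against NH among offspring of HC/LP fathers, all of them female. RSPH9 rose by 1.90 ± 0.32 (n = 6 against 6, adjusted p = 0.031), at least 1.38-fold over NH. GSONMT00040151001 (1.87, adjusted p = 0.011) and GSONMT00040877001 (2.70, adjusted p = 0.022, at least 1.89-fold) rose, and GSONMT00054239001 (-3.20, adjusted p = 0.022) and GSONMT00066913001 (-2.69, adjusted p = 0.045) fell. FADSD5 (4.39 ± 0.84, adjusted p = 0.059, at least 13.8-fold) and the thymosin gene TYB11 (2.50 ± 0.47, 0.058) did not pass. The FADSD5 difference again came from HH 3 to HH 6. The other 8 of the 5 highest and 5 lowest moderated statistics of named genes that did not pass were those of CYFP1 (1.04, 0.18), RTCB (0.84, 0.18, by another probe than the one given in HH against NN, which had 0.71), HSPB6L (1.05, 0.22), NMNA1 (-1.02, 0.18), PDE9A (-6.52 ± 1.52, 0.18), SWI5 (-2.73, 0.19), TPM4 (-0.62, 0.27) and COLI (-1.31, 0.27). In all, 15 probes passed, 11 higher and 4 lower, and 10 did with sex in the model. RSPH9 had 1.36, 2.67 and 1.67 on the 3 scan days, an adjusted p of 0.052 with scan day in the model, and 1.25 (adjusted p = 0.48) with array row, where 1 probe passed, while 3 passed with scan day. Fewer probes passed without HH 2 (9), NH 4 (5), HH 1 (3), NH 5 (3), NH 2 (2) and HH 5 (2), and RSPH9 lost the call without HH 1, HH 2, HH 5, HH 6, NH 1, NH 2, NH 5 or NH 6 (adjusted p up to 0.11). By camera and by fry 0 lists moved (smallest camera adjusted p = 0.86), and 0 members passed over all probes. Adjusted over the list alone 8 did. These were FADSD5, the cholesterol exporter gene ABCA1B (-0.47 ± 0.14), CGL (-0.66 ± 0.22) and ASSY (0.53 ± 0.19) of amino acid catabolism, the autophagy genes BNIP3 (-0.57 ± 0.21), SQSTM (-0.76 ± 0.31) and ATG4B (0.53 ± 0.22), and TOP2A (1.48 ± 0.58), alone in its list with an unadjusted p = 0.018.

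**Figure D2:**
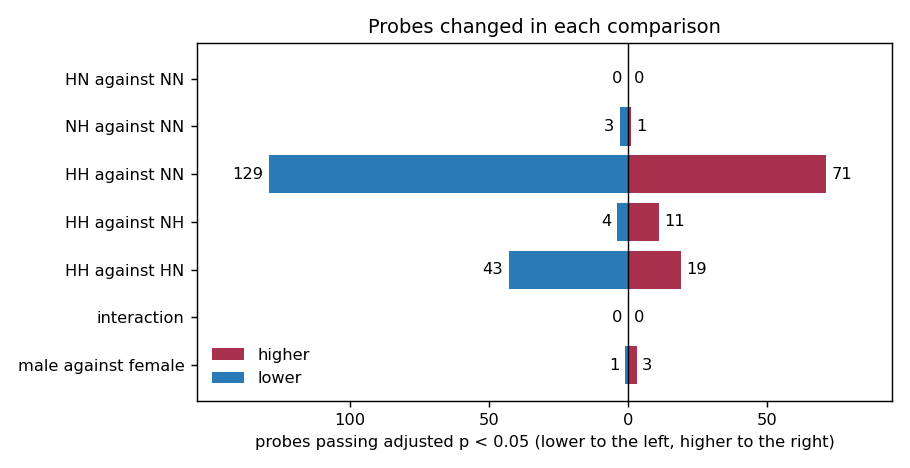
Bars give the number of probes past an adjusted p of 0.05 that were higher or lower in each comparison. HH against NN had 71 higher and 129 lower, HH against HN 19 and 43, and NH against NN 1 and 3.

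The mother's HC/LP diet alone was addressed by HN against NN, in which genes of the interferon and antiviral response were higher in HN, 5 of 5 members (median 0.47, camera adjusted p = 0.029). The list's adjusted p was 0.23 with an estimated correlation and 0.32 by fry. Its members included STAT2 (0.82 ± 0.36), IRF9 (0.51) and E2AK2 (0.47), and 0 of 5 passed, over the list alone or over all probes. Its median was 0.21, 0.36 and 0.24 on the 3 scan days, 0.50 with scan day in the model (adjusted p = 0.018), 0.37 with sex (0.019, or 0.17 with an estimated correlation as well) and 0.29 with array row (0.85), and row 1 held 5 of 5 HN and 1 of 6 NN arrays. With the mean of all probes of a gene its adjusted p was 0.22 and the call ended. Without NN 2, HN 2, HN 3, NN 4 or HN 4 its adjusted p was 0.1, 0.18, 0.093, 0.063 and 0.061. The number of lists called was 0 in those fits and 2 without NN 3 or NN 6. Leukocyte markers had 4 of 4 members higher in HN (median 0.22, adjusted p = 0.46).

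No single probe passed in HN against NN with limma (0 probes), and 1725 had an unadjusted p under 0.05, below the 2231 that chance gives. The 5 highest and 5 lowest moderated statistics of named genes were those of the transcription factor gene LEF1 (-2.12 ± 0.47, adjusted p = 0.42), TBCE (-1.20 ± 0.33), CLD12 (-0.68), SPRY4 (-1.88), UGT8 (-0.43), TSN16 (0.93), DAB2IPA (0.74), CIO1B (1.33), IRK11 (1.02) and RTCB (0.62). That RTCB probe is not the one given in HH against NN, which had 0.30 here. SPRY4 was well above background in 0 of 5 HN fish, so it was at least 1.59-fold lower there. FADSD5 had a fitted -0.39 ± 0.88, or 0.03 with sex in the model, and was well above background in 3 of 6 NN and 0 of 5 HN fish. When sex was added to the model 2 probes passed, and 2 did without HN 1. The cytosolic ribosome list was called as well once sex was added, higher in HN (median 0.20, adjusted p = 2.1e-06), but not with an estimated correlation as well (adjusted p = 0.17).

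Whether the effect of 1 parent's diet depended on the other's was tested by the interaction of both diets. FADSD5 had an interaction of 4.79 ± 1.22 (adjusted p = 1), with means of -4.25 in NN, -4.64 in HN, -4.51 in NH and -0.12 in HH, and no HN or NH fish was well above background. It passed adjusted over the list alone, as did TOP2A (1.89 ± 0.84, alone in its list with an unadjusted p = 0.034), and 0 list members passed over all probes. FADSD5 was among the 5 highest and 5 lowest moderated statistics of named genes, with CBX6 (1.35 ± 0.34), RSPH9 (1.66, with no NH fish well above background), FOXN4 (1.5), MSPD2 (0.93), PDE9A (-6.02), the mannose-binding lectin gene MBL2 (-1.44), ONCMYK-UBA (-0.84), SOX5 (-0.79) and PTPR2 (-0.74). With limma 0 probes passed, with or without sex in the model (1590 at an unadjusted p under 0.05), and 1 did without NH 5. By camera and fry 0 lists were called (smallest camera adjusted p = 0.39). The cytosolic ribosome list was called once sex was added to the model, with a median of -0.22 (adjusted p = 4.3e-06), but not with an estimated correlation as well (adjusted p = 0.37).

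Changes with the father's diet were set side by side in fish from control mothers and fish from HC/LP mothers. ECM1 had -2.32 in NH against NN and -3.13 in HH against HN, ONCMYK-UBA -0.58 and -1.42, and NPTN 0.87 and 2.16. The fitted values were -0.27 and 4.52 for FADSD5 and -2.0 and -0.34 for RSPH9, but FADSD5 was not well above background in any HN or NH fish, nor RSPH9 in any NH fish. As bounds on the group means, FADSD5 was at least 14.5-fold higher in HH than in HN and RSPH9 at least 1.48-fold lower in NH than in NN. The sizes thus cannot be set against each other. Of the 64 probes past the threshold in either comparison, 58 had the same sign in both (90.6%). Across the 44627 probes, which are not independent replicates, the correlation of the changes was 0.364 (Pearson) and 0.305 (Spearman), and 0 of 100 random regroupings of the fish reached it (highest 0.30). For the mother's diet, HN against NN and HH against NH correlated at 0.22 (Spearman 0.193), which 2 of 100 regroupings reached (highest 0.232), and 10 of 15 probes had the same sign (66.7%). Without NN 6 the mother's correlation was 0.126. With a filter on dim probes blind to the groups the correlations were 0.319 and 0.18, reached by 0 and 3 of 100 regroupings. No fish was shared within either pair, and the groups with an HC/LP mother lay mostly in row 1 of the slides. All 5 males were in NN (1) and HN (4), so sex ran the same way in both comparisons by the father's diet. Yet without NN 3, the only male in NH against NN, that comparison held females only. In all 23 fits without 1 array, that fit included, the father's correlation (Pearson) lay between 0.307 and 0.379. With sex in the model it lay within the 0.319 to 0.408 of the other settings. These values argue against sex as the source of the correlation.

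**Figure D3:**
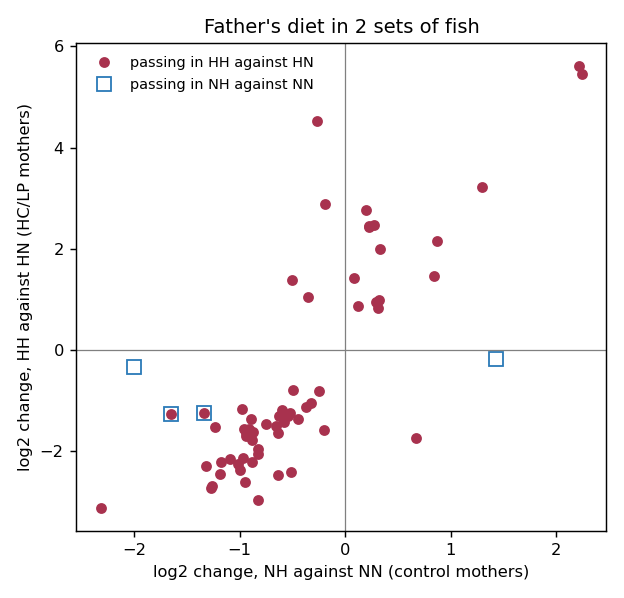
Each point is 1 of the 64 probes past an adjusted p of 0.05 in NH against NN (squares) or in HH against HN (filled circles), with the log2 change in NH against NN on the horizontal axis and in HH against HN on the vertical axis. The sign was the same for 58 of them.

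Sex was compared as male against female within the groups, with 4 males and 1 female in HN and 1 male and 5 females in NN. The HN female, HN 2, had the lowest share of features well above background (50.9%), so sex and array quality cannot be told apart within HN. Genes of the cytosolic ribosome were lower in males, 33 of 49 members (median -0.26, camera adjusted p = 6.8e-08), with an adjusted p = 0.17 with an estimated correlation. By fry the adjusted p was 0.11, or 0.008 for change in either direction. Adjusted over the list alone, 9 ribosomal genes passed, among them RS16 (-0.91 ± 0.22), RL24 (-0.89 ± 0.27) and RS14 (-0.60 ± 0.16), as did STAT2 (-1.21 ± 0.39), against 0 over all probes. The median of the list was -0.25 with scan day in the model (adjusted p = 6.2e-08) and -0.24 with array row (9.1e-08). On scan day 3, the only day on which a group held both sexes, it was -0.14. With limma 4 probes passed, 3 higher and 1 lower, none with a gene name. Of these, GSONMT00038825001 (2.86 ± 0.45) and GSONMT00009585001 (2.78 ± 0.43) rose and GSONMT00029049001 (-1.46 ± 0.22) fell (adjusted p = 0.041 each). Among the 5 highest and 5 lowest moderated statistics of named genes, besides RS16, were MYCBPAP (1.69 ± 0.29, adjusted p = 0.076), GOSR2 (1.05), ST1S3 (1.68), STCH (1.24), PAM (1.21), GANAB (-1.16 ± 0.24, 0.21), PPIA1 (-0.90), ACBD7 (-2.10) and TTBK2 (-1.96). The count rested on few fish: it was 200 without NN 3, 38 without HN 2, 2 without NN 2, 1 without HN 4 or NN 6, and 0 without NN 1, NN 4, NN 5, NH 1, NH 2, NH 5, NH 6, HN 1, HH 2 or HH 3. It was 0 with scan day in the model, with array weights, with only HN and NN in the fit, and with no filter on dim probes or one blind to the groups. Lists called numbered 2 without HN 2.

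With sex in the model, the cytosolic ribosome list was also called in HH against HN, lower in HH (median -0.25, adjusted p = 3.9e-05, or 0.36 with an estimated correlation as well), where its median without sex was -0.04 (adjusted p = 0.71). The hepatocyte markers ALB1, PROX1A and PROX1B had a median of -0.13 in males against females, and markers of leukocytes 0.17 and of stroma and endothelium -0.32, and none of these lists passed in any comparison.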

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

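The tests of array row, scan day, single fish, sex and parental diet below were chosen after the result was seen, while those of signal near the background and of several probes on 1 transcript were written before. The level of CIO1B in the fish NH 6 was -4.18, apart from the other NH fish, which lay between -2.98 and -2.72. The gap to the nearest fish was 0.83 of the range of the group. It was the only such value in 88 groups tested, where chance alone would give about 1 in 20 groups, or 4.4.

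HH against NN changed 200 probes, among them ECM1, FADSD5 and ONCMYK-UBA. HN arrays lay in the same slide row as most HH arrays, yet HN against NN showed a median of only 22.5% of the HH against NN change (quartiles 3.4% to 46.2%, 200 probes). The NN fish common to both comparisons push this share up, and the choice of probes by their HH against NN change pushes it down. Array row on the slide is thus unlikely to account for the whole change, but the share is no clean test. It also says nothing about slide column, as most HH arrays lay in column 4 and most HN arrays did not. With row in the model the median absolute change was 1.48 after 1.54 and the SE 0.38 after 0.30, and 11 of the 200 probes still passed, since row and mother's diet nearly coincide, so that a part played by row stays open. The HH and NN arrays were spread evenly over the scan days, so a shift by day cancels between these groups. The fit with scan day, in which 176 of the 200 still passed, was therefore no test of day as the source. For on and off differences between single fish, 3% of the passing probes (6 probes) had a gap of 2 log2 units. This gap is wider than the median change of 1.54, so that the test of such differences decides nothing. The diets of the parents remain a possible explanation. So do slide column, which was not tested, and tank and family of the fish, which the labels do not give.

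In HH against HN, 62 probes passed, and 2 of them did with sex in the model. The sex of the fish was weighed because HN held 4 males and HH none. Once sex was in the model a median of 97.3% of the change was left (quartiles 89.6% to 109.8%), the median absolute change being 1.65 after 1.67, while the median SE grew from 0.32 to 0.46, so the calls ended because of the wider error and not because of smaller changes. The sex term rests on 1 female in HN and 1 male in NN. That female, HN 2, had the lowest share of features well above background of all arrays (50.9%, against 62.6% to 80.5% in the HN males). The 62 probes were also chosen for this change, which favours probes in which the HN fish agree, the female included. The share left therefore does not settle whether sex was the source. The transcript model GSONMT00039314001, chosen after its values were seen, had 5.45 and then 4.23 with sex in the model. Sex, diet of the father, tank and family stay open.

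A set of 112 probes (0.25% of those tested) was on in some fish and off in others, with a gap of at least 2 log2 units between 2 sets of at least 3 fish, and 11 of them had a gene name, among them FADSD5, PDE9A, LIPH and SSRB. Signal near the background does not explain the on fish, as 0.9% of the probes had an on fish that was not well above background. The filter and the gap favour this result, and the off fish were not tested, so a part of background in the width of the gap stays open. Of these probes, 0% were on or off in all fish of each group. Yet over the 130 such probes left by a filter blind to the groups, the groups held a mean of 28.1% of the on and off variance, which 0 of 1000 regroupings of the fish reached (mean 13.6%, highest 22.7%), so a part of parental diet, or of family or tank going with it, stays a possible explanation. The on fish recurred: 9 sets of fish held 37 of the probes, up to 7 probes each, where random draws (1000) gave sets of at most 2. Several probes on 1 transcript could give such sets, and 10.1% of 79 probe pairs with the same on fish (8 pairs) shared 20 bases, which leaves this open because probes on different parts of a transcript need not overlap, and a variant shared by these fish was not tested.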

How the results depend on the processing

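The fit of the shared slides without the slide term, the comparisons by 1 parent's diet over all fish, the list tests with sex and an estimated correlation together, and the filter on dim probes blind to the groups, were chosen after seeing the data. Direction was followed for the named genes that passed and the lists called, and none of these tests turned, but the median of oxidative phosphorylation in HH against HN went from -0.23 to 0.09 with sex in the model, its test still down. Among genes that did not pass, FADSD5 went from -0.39 to 0.03 and D6FADC from -0.02 to 0.38 in HN against NN with sex in the model. Of the values tried besides the first fit, 1007 kept direction and side of the threshold or stayed within 1.5 times (counts) or within the spread of the regroupings (correlations), 273 lost a call and 151 counts moved by over 1.5 times. For the counts below the cause was not tested except where a model term or a smaller set of arrays or probes is named.

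With quantile normalization NH against NN had 2 probes and HH against NH 4, and with cyclic loess NH against NN had 2. With normexp background correction the counts were 2 (NH against NN), 118 (HH against NN), 4 (HH against NH), 28 (HH against HN) and 1 (male against female), and with the values of the authors' table they were 1, 123, 4, 2 and 2. With no filter on dim probes, NH against NN had 2, HH against NN 133, HH against HN 14 and male against female 0, with a filter blind to the groups male against female had 0, and with probes well above background on all arrays NH against NN had 2 and HH against NH 6. With only the groups in the contrast, NH against NN had 2, HH against NH 3, HH against HN 140 and male against female 0.

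With sex as a covariate, HN against NN had 2 probes, NH against NN 7 and HH against HN 5, and the lists called were 2 in HN against NN and 1 in the interaction. In females only, where HN is 1 fish assumed to vary like the others, the counts were 154 (HN against NN), 2 (NH against NN), 90 (HH against NN), 153 (HH against HN) and 40 (interaction), and the lists 3, 2 (HH against HN) and 2 (interaction). Slide as a random block gave 390 in HH against NN, and slide as a fixed block gave 10, with 165 for the same 10 arrays without the block. Array row as a covariate gave 12 (HH against NN), 1 (HH against NH) and 29 (HH against HN), and scan date 3 (HH against NH), 38 (HH against HN) and 0 (male against female). Array weights gave 512 (HH against NN), 34 (HH against NH), 192 (HH against HN) and 0 (male against female). An estimated correlation called 0 lists in HN against NN, 0 in HH against HN and 0 in male against female, fry 0, 0 and 0, fry for either direction 0 in HN against NN and 0 in HH against HN, and the mean of all detected probes of a gene 0 in HN against NN. Sex as a covariate and an estimated correlation together called 0 in HN against NN and 0 in HH against HN.

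Leaving out 1 array at a time, the probes passing ranged from 0 to 2 (HN against NN), 1 to 36 (NH against NN), 68 to 272 (HH against NN), 2 to 17 (HH against NH), 3 to 74 (HH against HN), 0 to 1 (interaction) and 0 to 200 (male against female), and the lists called from 0 to 2 (HN against NN), 0 to 1 (HH against HN) and 1 to 2 (male against female). The correlation of the mother's contrasts ranged from 0.126 (without NN 6) to 0.24 and that of the father's from 0.307 to 0.379. For named genes 372 of 548 such values still passed and 176 did not. Signal over background limits the dim genes: FADSD5 was not well above background in any HN or NH fish, nor RSPH9 in any NH fish, so that their fitted changes there are no measured sizes and only the bounds given as at least N-fold hold. PTA1 was well above background in 1 of 6 NN fish, and C5AR was well above background in 1 of 6 HH fish. No paired analysis was possible by replicate number because these were given in order of the samples and pair no fish; the shared slides of HH and NN gave the fixed block above.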

Other observations

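All comparisons of fish by 1 parent's diet, and the counts over other splits of the fish, are tests chosen after the results were seen. Taken over both kinds of mother, fish with an HC/LP father had lower ECM1 (-2.73 ± 0.36, log2, SE, n = 12 against 11, limma adjusted p = 0.0021), lower ONCMYK-UBA (-1.0 ± 0.15, adjusted p = 0.0055) and lower RTDR1 (-0.98 ± 0.14, adjusted p = 0.0039) than fish with a control father, in 11, 12 and 12 of 12 fish. C5AR (-1.69), CR19B (-1.83), FXYD6 (-1.53), the actin-binding coactosin gene COTL1 (-1.17), SMD3 (-0.91), PLM (-0.66), CBL (-0.52) and SPD2B (-0.44) also fell, and BRI3B (2.29), NPTN (1.51), CIO1B (1.34), RTCB (1.30) and VPS41 (1.24) rose, with adjusted p from 0.015 to 0.043. C5AR was well above background in 4 NN, 2 HN, 1 NH and 1 HH fish. RSPH9 (-1.17, adjusted p = 0.024) also passed, in the direction of the change in 9 of 12 fish, but its means were -5.35 in NH, where it was well above background in 0 fish, and -3.45 in HH, against -3.35 in NN and -3.11 in HN. In all 226 probes passed, 55 higher and 171 lower, 17 of them named, with a median absolute change of 1.11. By the mother's diet 19 probes passed, 7 higher and 12 lower, and the 1 named gene was the B-cell activating cytokine gene TNFSF13B (-1.36 ± 0.25, adjusted p = 0.041, lower in 11 of 11 fish).

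The 226 probes were chosen over all days, which pushes their agreement by day up (226 of 226 on each). When 226 probes were chosen on the other days, 208, 192 and 197 had the same direction on scan days 1, 2 and 3 (92%, 85% and 87.2%, against 64.8%, 61.2% and 59.4% of all probes), with 0, 14 and 0 probes passing on a single day. With array row in the model 176 probes passed for the father's diet, 168 of them shared with the 226, and 0 for the mother's diet, where TNFSF13B had -1.23 (adjusted p = 0.6). When sex was in the model 48 passed for the father's diet, 25 of them shared, as the median SE grew from 0.22 to 0.29 and the change went from 1.11 to 1.08, and 7 passed for the mother's. ONCMYK-UBA (adjusted p = 0.01) and RTDR1 (0.023) still passed with sex, and the other 15 of the 17 named genes did not (adjusted p from 0.053 for ECM1 and CIO1B to 0.36 for SPD2B), nor did TNFSF13B (0.1). RTCB (0.059), SPD2B (0.054) and CBL (0.061) did not pass with array row. All 5 males had a control father, so sex went with the father's diet. A fit of females only leaves 1 HN fish, so it does not settle the part of sex. For the father's diet, normexp gave 95 probes, the authors' values 91, no filter on dim probes 141 and array weights 426. For the mother's diet, quantile normalization gave 32, normexp 11, slide as a random block 36 and array weights 36. Leaving out 1 array gave 128 to 379 probes for the father's diet, namely 128 without NH 1, 131 without NN 1, 135 without HN 1 or NN 4, 143 without HH 5, 146 without HH 2, 148 without HH 3, 149 without HH 4 and 379 without NH 6. For the mother's diet the counts were 4 without HH 5, 5 without HH 1 or HN 4, 7 without NN 1, 10 without NH 2, 12 without HN 3 or NN 4, and 33 without NN 3 or NH 6.

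Among the lists with 1 or 2 members, which were too small for the test, the medians in HH against NN were -0.44 for fatty acid synthesis (SCD5), 0.22 for peroxisomal fatty acid oxidation (HSD17B4), 1.51 for triglyceride and lipid droplet (MGLL), -0.09 for bile acid synthesis and transport, -0.09 for gluconeogenesis and glycogen, and -0.74 for the cell cycle (TOP2A). The globin gene HBB1 had means of 8.60 in NN, 8.35 in HN, 8.03 in NH and 8.21 in HH, and the albumin gene ALB1 6.31, 6.48, 6.27 and 6.33.

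Each count was set against other splits of the same fish, 100 in all with the real one, or 30 for sex. For the probes of HH against NN, 1 split, the real one, reached the count (200 against at most 1 in other splits). The same held for HH against NH (15 against 6) and HH against HN (62 against 14). It also held for the father's diet (226 against 1) and the mother's diet (19 against 2). The filter on dim probes used the real groups, and with a filter blind to them (50463 probes) the counts were 181 against 1, 10 against 2, 44 against 11, 187 against 1 and 19 against 2. A chance draw of single fish is therefore unlikely, but a tank, family or place on the slides shared within a group could also make the real split stand out. Without single arrays, HH against NH fell to as few as 2 probes and HH against HN to 3. With array row in the model HH against NH had 1 and the mother's diet 0, so these counts are not firm. For male against female 1 of 30 splits, the real one, reached the count (4 against 2), but this count was 0 with scan day in the model, with array weights, with no filter on dim probes or one blind to the groups, with only the groups compared, and without some single arrays, so little rests on it. Chance cannot be excluded for NH against NN, where 8 splits had 4 probes or more and 1 had 111. The latter may reflect a structure of the samples other than the groups, but this rests on 1 split. That split set NN 1, NN 3, NN 4, NN 6, NH 2 and NH 3 against the rest, with 1 array of row 1 on each side. The named side held 1 array of scan day 1 against 3, 2 of day 2 against 2 and 3 of day 3 against 1. It also held the 1 male, and what the split follows was not tested. For HN against NN (0 against 1) and the interaction (0 against 3) a count of 0 is reached by any split (100 of 100), so the splits say nothing about chance. For the lists called, 39 splits had as many as HN against NN (1 against 4), 45 as many as HH against HN (1 against 4) and 10 of 30 as many as male against female (1 against 2), so chance cannot be excluded. For the comparisons with 0 lists called the splits say nothing either, since all 100 reach 0, the highest being 3 for NH against NN, HH against NN and HH against NH, 4 for the interaction, 2 for the father's diet and 4 for the mother's.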
